A study of Mus musculus with 111 samples.

How the data were processed

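Per the labels, gastrocnemius muscles of male C57BL/6 mice were taken 2, 7 or 14 days after casting of the right hindlimb, cutting of an Achilles tendon or sham surgery, and from naive mice. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, and biotin-labelled cRNA was made from 6 ug of total RNA by the standard Affymetrix protocol and hybridised to 1 array per muscle. The deposited values are linear signal intensities that the authors computed with MAS5 and GCOS, per the labels' processing entries, which state neither the version of either program nor the target of the scaling. The mean signal of each array after trimming 2 percent at each end lay between 99.955 and 99.965, so the values had been scaled to a common mean near 100 before deposit. The deposited matrix held 45101 probe sets, 64 of them array controls, and 111 arrays with 0 missing values. Signals ran from 0.0116 to 27000, and the median signal of an array lay between 16.14 and 26.36. No pair of arrays was identical, and correlations between arrays on the log2 scale lay between 0.9053 and 0.984. The values are relative signals, so absolute amounts of RNA cannot be read from them, and the number of arrays limits precision.

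Each array's group, day, leg and animal came from its label. The animal numbers and leg sides in the labels gave 41 animals with both legs, 25 in casting and 16 in tenotomy. The pairing was checked on the residuals of each gene around its group mean. The mean correlation between the legs of the same animal was 0.0634 over 41 pairs, with 13 pairs over 0.1 (0.0657 and 9 in casting, 0.0597 and 4 in tenotomy), against -0.0099 over 260 pairs of legs from different animals of the same cohort and day, with 34 over 0.1. For sham animals at day 2 the treatment entry of the labels is n/a, and their group was taken from the sample title. The design text and the sample labels disagree on the operated leg of the tenotomy animals, and the sample labels were used, with the other reading as an alternative. Animals are numbered separately in each cohort, so that casting, tenotomy and the sham and naive animals cannot be separated from their cohorts. In each model the leg side goes with the treatment.

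Signals were analysed as log2 of the signal plus 3.984, the 20th percentile of all values. Probe sets were assigned to genes by the platform annotation. Of the probe sets 34958 listed a single gene, 932 listed several and 9211 listed none, and the probe sets with 1 gene were used. The gene identifier of 34754 of them was found in the reference gene table, whose symbol was used, and the others kept the symbol of the annotation. A probe set was tested when its signal was above the array's 40th percentile (a signal of 9.649 to 17.84) in at least 5 arrays. For each gene the probe set with the highest mean was kept, which gave 16029 tested genes of 18194 with a probe set. Analyses used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for figures.

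One limma model held a mean for each of the 16 groups, with the animal as a random block (consensus correlation 0.0964) and moderated variances with an intensity trend (prior degrees of freedom 8.6303). There were 19 comparisons. They were treated against control legs in each model and day, the difference of these between the models at each day and between days 14 and 2 in each model, labelled tenotomy legs against sham at each day, sham against naive at each day, and the control legs of each model, averaged over days, against naive. P values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. Differences between legs in distance from naive and in RNA quality were tested by flipping signs within pairs, exactly for 16 pairs and by random permutation for 25.

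The comparisons, lists, the rule for named genes and the alternative settings were fixed before the data were examined. There were 21 gene lists covering muscle ubiquitin ligases, the 26S proteasome, the immunoproteasome, cathepsins and the lysosome, autophagy, calpains and caspases, extracellular proteases, extracellular matrix, fast and slow fibre proteins, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, glycolysis, the neuromuscular junction, myogenic regeneration, mechanical stress, growth signalling, oxidative stress, complement and proliferation. There were 9 marker lists for macrophages, neutrophils, lymphocytes, fibroblasts, tenocytes, adipocytes, endothelial cells, Schwann cells and erythroid cells, the last with fewer than 5 tested members and therefore not tested. Some genes belong to more than 1 list. Lists were tested with cameraPR at a preset correlation between genes of 0.01, with the correlation estimated from residuals, and with the self-contained test fry, and adjusted over the 29 lists of a comparison. Counts described as adjusted over the list alone came from adjusting the p values of its members only.

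Genes were named by a rule in several parts. A fixed set of 11 genes of the degradation, fibre type, denervation and growth programmes was always named, of which 10 were tested, and the other is not reported here. The 6 largest rises and 6 largest falls past the threshold were named, for the leg comparisons only if they went the same way in every animal with both legs. Up to 2 risen and 2 fallen members of each list were named, and for the comparisons with sham or naive the 5 largest changes each way. Part of the genes so named are described. The values of always-named genes in the comparison of day 14 with day 2 lie outside this rule and were chosen after they were seen.

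The alternative settings were no block for the animal, the animal as a fixed replicate block with the paired legs only, no pseudocount with values under 1 set to 1, a pseudocount 4 times as large (15.936), no filter (18194 genes), a stricter filter at the 60th percentile (11540 genes), quantile normalization, the mean of a gene's probe sets, only the groups compared, array weights, and leaving out each array in turn of groups with 5 or fewer arrays. Chosen after the data were seen were the tenotomy legs taken by side with the right leg as operated, the omission of 8 arrays in 5 groups whose 5th percentile of signal was raised (the median over all arrays was 0.91), and the actin 3' to 5' ratio as a covariate. Counts were also compared with other groupings of the same arrays, at most 100 per comparison.

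The procedure was tested on simulated data with normally distributed noise of each gene's spread in these arrays, in which 100 of 16029 genes were changed by a log2 size of 0.5 and 100 by 1. For casting at day 2, 55 and 90 of 100 were found with 3 false calls, for casting at day 7, 47 and 83 with 9, for tenotomy at day 14, 41 and 68 with 4, for sham at day 2 against naive, 23 and 57 with 5, and for tenotomy against casting at day 2, 19 and 56 with 3. Probe sets that list several genes or none were left out. No array was left out of the results other than in the alternatives.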

Results

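Gene expression was measured in gastrocnemius muscle of male C57BL/6 mice after hindlimb casting or after cutting of the Achilles tendon (tenotomy), and in sham-operated and naive mice. Each of the 111 arrays held 45101 probe sets and the RNA of 1 muscle, and the muscles came from 70 mice. Casting gave 10 cast and 9 control legs at day 2, 7 and 8 at day 7, and 9 and 9 at day 14. The tenotomy animals gave 5 legs labelled tenotomy and 5 labelled control at day 2, 7 and 7 at day 7, and 5 and 5 at day 14. Sham operation gave 3, 7 and 8 muscles at these days, and 7 muscles came from naive mice. Muscles of both legs were present for 25 casting and 16 tenotomy animals. The number of arrays in a group limited the precision of every value below.

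The labels conflict on which leg of the tenotomy animals was operated. The design text says that the right tendon was severed and the left leg was the control, whereas the sample labels give tenotomy to the left legs and control to the right legs. The sample labels were kept, and each tenotomy value below is the leg labelled tenotomy (left) minus the leg labelled control (right). The right leg lay farther from the naive mean than the left leg in 16 of 16 tenotomy pairs (root mean square log2 distance 0.675 and 0.518, difference 0.157 with SD 0.078, exact sign-flip p = 3.05e-05). Among the casting animals the cast right leg lay farther in 17 of 25 pairs (0.573 and 0.508, difference 0.064 with SD 0.086, permutation p = 6.90e-04). The beta-actin 3' to 5' log2 ratio, a sign of RNA quality, was also higher in the right legs of 15 of 16 tenotomy pairs (difference 0.628, SD 0.442, exact p = 1.22e-04). The same ratio for Gapdh differed by 0.017 with SD 0.076 (exact p = 0.377), and the casting pairs differed in the actin ratio by -0.17 with SD 0.349 (permutation p = 0.0227).

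**Figure D1:**
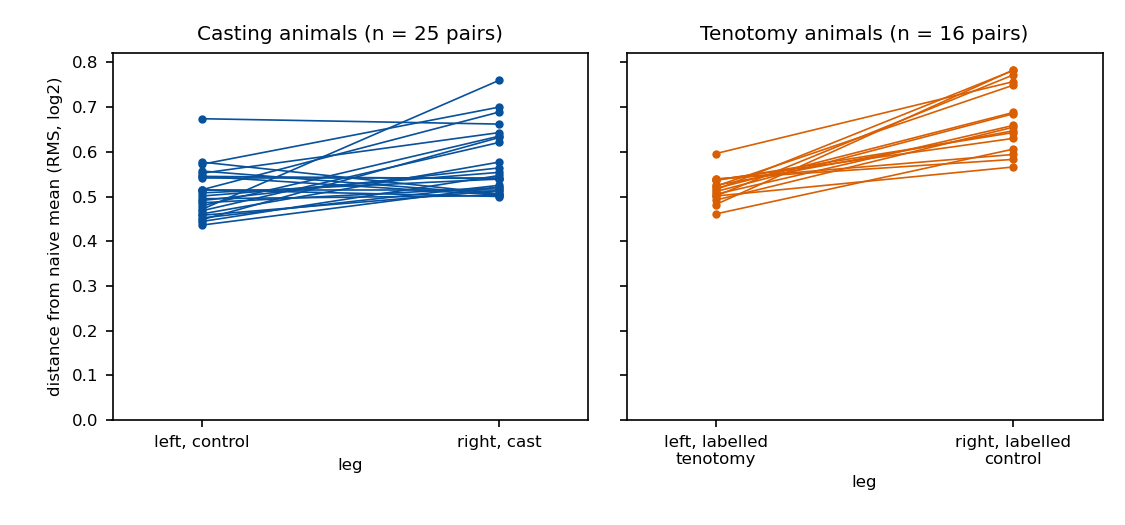
Root mean square log2 distance of each muscle from the naive mean over all tested genes (vertical axis, log2 units), for the left and right legs of 25 casting and 16 tenotomy animals; each line joins the legs of 1 animal. The right leg is farther in 17 of 25 casting pairs and 16 of 16 tenotomy pairs.

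The question asked at day 2 of casting was which genes the cast leg expressed differently from the control leg of the same animals. Among the muscle ubiquitin ligases, which mark proteins for breakdown, Fbxo32 and Trim63 rose in every animal with both legs. Fbxo32 (atrogin-1) rose by 1.45 on the log2 scale (SE 0.19, adjusted p = 1.16e-09, 9 of 9 pairs), and Trim63 (MuRF1) by 0.93 (SE 0.13, adjusted p = 2.02e-09, 9 of 9). The mean signal of Fbxo32 was 3859.6 in cast legs (SD 1045.2, n = 10), 1421.6 in control legs (SD 494.1, n = 9) and 765.8 in naive muscle (SD 294.1, n = 7). The subunits of the 26S proteasome, the complex that degrades ubiquitin-tagged proteins, rose nearly as a whole. Of 37 subunits 31 were up and 1 down, the same adjusted over the list alone, with a median of 0.37 (adjusted p = 2.87e-27, and 0.0135 with an estimated correlation). The ATPases Psmc1 and Psmc4 of its cap rose by 0.71 and 0.66. Relative to naive muscle the list mean was 0.33 in the cast legs (SD 0.17, n = 10) and 0 in the control legs (SD 0.09, n = 9). The lysosomal protease Ctsl rose by 0.49 (SE 0.08, adjusted p = 9.49e-07). The cathepsin and lysosome list as a whole was not called, with 5 up and 7 down of 32 (adjusted p = 0.867).

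Other parts of the degradation and repair programme moved at day 2 of casting as well. Of the 27 muscle ubiquitin ligases 12 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.0016, and 0.233 with an estimated correlation). The kelch proteins Kbtbd13 and Klhl40, adaptors of cullin ligases, stood at -0.68 and -0.37. Autophagy genes had 11 up and 5 down of 33, or 14 and 5 adjusted over the list alone (adjusted p = 0.0015, and 0.102 with an estimated correlation). The autophagy kinase Ulk1 rose by 0.65. Mechanical stress and chaperone genes fell, 17 of 24 with 1 up, or 18 and 1 adjusted over the list alone (adjusted p = 6.54e-10, and 0.102 with an estimated correlation). They were led by the stretch-sensitive sarcomere proteins Csrp3 (-2.74, SE 0.31) and Ankrd2 (-1.93, SE 0.25) and the heat shock protein Hspa1b (-2.20, SE 0.29), each lower in 9 of 9 pairs. Genes with the largest rises included the cold-inducible RNA-binding protein Cirbp (1.83, SE 0.13), Arrdc4 (1.79, SE 0.14), which limits glucose uptake, and Depp1 (1.87, SE 0.30), a target of FOXO factors. Chrna1, the acetylcholine receptor subunit that rises on denervation, was up by 0.66 (SE 0.13, adjusted p = 2.17e-05, 9 of 9), with Gadd45a up by 1.25 and the deacetylase Hdac4 by 0.91. Its list was not called, with 5 up and 1 down of 21, or 5 and 3 adjusted over the list alone (adjusted p = 0.239).

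Matrix and macrophage genes were lower in the cast leg than in the control leg at day 2. The macrophage list mean lay above naive muscle in the legs of each kind, and farther above it in the control legs. Extracellular matrix genes had 18 of 34 down and 1 up, or 21 and 1 adjusted over the list alone (adjusted p = 5.78e-06, and 0.723 with an estimated correlation). The proteoglycan Vcan stood at -1.19 and the collagen chaperone Serpinh1 at -1.43. Macrophage and monocyte markers had 12 of 26 down and 1 up, or 16 and 1 adjusted over the list alone (adjusted p = 0.0019, and 0.723 with an estimated correlation). The cytokine Ccl2 was down by -1.19 and the lysosomal glycoprotein Gpnmb was the member that rose (0.86). Complement genes had 7 of 14 down, the same adjusted over the list alone (adjusted p = 0.0216, and 0.723 with an estimated correlation), a call that ended with the stricter filter (adjusted p = 0.061) and with only the groups compared (adjusted p = 0.0602). Myh4, Myh7, Foxo1, Mt2, Myog and Cdkn1a did not pass (-0.38, 0.03, 0.18, -0.73, -0.21 and 0.28, adjusted p = 0.0914, 0.964, 0.308, 0.146, 0.317 and 0.374). The remaining lists, among them calpains and caspases, extracellular proteases, fast and slow fibre proteins, the immunoproteasome and the energy pathways, had adjusted p of 0.0515 or more. In some alternative settings the fast fibre, fibroblast, extracellular protease, oxidative phosphorylation, calpain and neuromuscular lists were called (adjusted p = 0.0026 to 0.0418). Median, mean and test differed in sign for the tricarboxylic acid cycle, oxidative stress, lymphocyte and Schwann cell lists, none of them called. In all, limma called 3893 genes at day 2 (1757 up, 2136 down). With the legs swapped at random within animals as many were reached in 1 of 100 splits, the real one.

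At day 7 of casting the comparison asked which of these differences were present after a week. Fbxo32 was still higher in the cast leg by 0.88 (SE 0.22, adjusted p = 0.00295, 7 of 7 pairs), although the call ended without the arrays with a raised low end (adjusted p = 0.0673). Trim63 (0.16, adjusted p = 0.607) and Ctsl (0.21, adjusted p = 0.17) did not pass. Proteasome subunits stood higher, 16 of 37 with none down, or 26 and 1 adjusted over the list alone (adjusted p = 4.31e-15, and 0.0812 with an estimated correlation). The list mean from naive was 0.08 in cast and -0.12 in control legs. Psmd4 was up by 0.51. The oxidative machinery fell: fatty acid oxidation 14 of 22, the tricarboxylic acid cycle 8 of 19 and oxidative phosphorylation 16 of 44, with none up, or 16, 12 and 21 adjusted over the list alone. Their list adjusted p were 4.31e-15, 1.93e-11 and 1.03e-13 (adjusted p = 0.0594, 0.0812 and 0.345 with an estimated correlation). Fabp3, the fatty acid carrier of oxidative fibres, fell by 1.07 and Acaa2, a beta-oxidation enzyme, by 0.72. Slow fibre proteins had 6 of 17 down, or 7 adjusted over the list alone (adjusted p = 6.41e-07, and 0.129 with an estimated correlation). The calcium store protein Casq2 stood at -1.51 and the slow myosin light chain Myl2 at -1.10. Mechanical stress genes had 12 of 24 down, or 15 down and 1 up adjusted over the list alone (adjusted p = 8.60e-12, and 0.0594 with an estimated correlation), with Csrp3 at -1.96 and Ankrd2 at -1.79.

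Receptor and macrophage genes stood higher in the cast leg at day 7. Neuromuscular junction and denervation genes had 4 of 21 up, or 5 adjusted over the list alone (adjusted p = 0.0177, and 0.129 with an estimated correlation), with the receptor subunits Chrnb1 (0.80) and Chrna1 (0.66, SE 0.14, adjusted p = 6.66e-04). Macrophage markers had 5 of 26 up, the same adjusted over the list alone (adjusted p = 1.31e-04, and 0.419 with an estimated correlation). The call ended with fry (adjusted p = 0.0711), and the galectin Lgals3 rose by 1.08. Schwann cell markers had 2 of 8 up, or 3 adjusted over the list alone (adjusted p = 0.0117, and 0.345 with an estimated correlation), and neutrophil markers had a median of 1.13 with no member passing (adjusted p = 0.008, and 0.362 with an estimated correlation). Extracellular matrix genes had 2 of 34 down (adjusted p = 2.07e-06, and 0.362 with an estimated correlation) and glycolysis 1 of 20 (adjusted p = 0.0202, and 0.541 with an estimated correlation). Myogenic regeneration had 4 of 16 down and 1 up (adjusted p = 0.03, and 0.345 with an estimated correlation), and each of these counts was the same adjusted over the list alone. The matrix call ended with fry (adjusted p = 0.0596) and the other 2 with array weights (adjusted p = 0.0834 and 0.234). Actc1, the cardiac actin of immature fibres, was 2.52 below the control leg, the largest gap among genes lower in every pair. Embryonic Myh3 was 2.13 above naive in control legs averaged over days. Median and mean differed in sign for the uncalled extracellular proteases, and the other lists had adjusted p of 0.059 or more. In some alternative settings the autophagy, growth signalling, fibroblast, tenocyte, adipocyte, lysosome and proliferation lists were called (adjusted p = 0.0076 to 0.0477). There were 1406 genes past the test (676 up, 730 down), against 2470 with array weights and 796 without the arrays with a raised low end. With legs swapped within animals 2 of 100 splits gave as many, counting the real one, with up to 1508 genes.

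The day 14 comparison asked how the cast leg stood after 2 weeks. Fbxo32 (0.38, adjusted p = 0.211) and Trim63 (0.03, adjusted p = 0.93) did not pass, and the proteasome list had 3 up and 2 down of 37 (adjusted p = 0.468), although it was called up with quantile normalization (adjusted p = 0.0015). Macrophage markers rose, 22 of 26 with none down, or 23 adjusted over the list alone (adjusted p = 5.10e-16, and 0.124 with an estimated correlation), including Lgals3 (1.43) and the chemokine Ccl8 (1.89). Relative to naive muscle the macrophage list mean was 0.57 in control legs (SD 0.27, n = 9) and ranged from 0.90 to 2.10 in the 9 cast legs. Complement genes had 9 of 14 up, or 12 adjusted over the list alone (adjusted p = 3.69e-07, and 0.139 with an estimated correlation). Extracellular proteases and inhibitors had 10 of 30 up, or 17 up and 1 down adjusted over the list alone (adjusted p = 4.12e-06, and 0.218 with an estimated correlation). The serpin Serpina3n rose by 2.58 (SE 0.41) and the stromelysin Mmp3 by 1.83. Lysosomal genes had 12 of 32 up and 2 down, or 13 and 2 adjusted over the list alone (adjusted p = 0.0051, and 0.479 with an estimated correlation). The proteases Ctss and Lgmn rose by 0.89 each. The metallothionein Mt2, which binds zinc, rose by 1.85 (SE 0.37, adjusted p = 1.77e-04), and the cytokine Il6 by 1.60.

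The oxidative lists were again lower at day 14 of casting. Fatty acid oxidation had 13 of 22 down, or 17 adjusted over the list alone (adjusted p = 1.74e-15, and 0.0709 with an estimated correlation), with Fabp3 at -0.79 and Acaa2 at -0.58. The tricarboxylic acid cycle (6 of 19 down, 8 adjusted over the list alone) and oxidative phosphorylation (4 of 44, the same adjusted over the list alone) each had adjusted p = 4.19e-06 (adjusted p = 0.311 and 0.645 with an estimated correlation), and the latter call ended with fry (adjusted p = 0.173). Slow fibre proteins had 6 of 17 down, or 10 adjusted over the list alone (adjusted p = 3.12e-06, and 0.218 with an estimated correlation). The slow troponin Tnni1 stood at -1.10 and Casq2 at -0.95. Myh7, the slow myosin, was lower by a small margin (-0.83, adjusted p = 0.0469), a call that ended in 6 alternative settings (adjusted p = 0.0519 to 0.178). Neuromuscular junction genes had 5 of 21 up, or 7 adjusted over the list alone (adjusted p = 0.0386, and 0.222 with an estimated correlation). Runx1, a transcription factor of denervated muscle, rose by 0.93 and Chrnb1 by 0.87. Chrna1 (0.59, adjusted p = 7.47e-04), Myog (0.47, adjusted p = 0.017) and Ctsl (0.27, adjusted p = 0.0191) rose too. These calls ended, in that order, with only the groups compared (adjusted p = 0.073), without the arrays with a raised low end (adjusted p = 0.0531) and with the mean of a gene's probe sets (adjusted p = 0.939).

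Smaller shifts at day 14 of casting involved matrix, stress and dividing-cell genes. Extracellular matrix genes had 7 of 34 up and 1 down, or 11 and 1 adjusted over the list alone (adjusted p = 0.0467, and 0.795 with an estimated correlation). The call ended in 5 settings, and the collagen cross-linking oxidase Lox rose by 1.09. Proliferation genes had 4 of 31 up and 1 down, or 9 and 2 adjusted over the list alone (adjusted p = 0.0043, and 0.476 with an estimated correlation). Mechanical stress genes had 6 of 24 down and 1 up, or 7 and 1 adjusted over the list alone (adjusted p = 0.0039, and 0.479 with an estimated correlation), a call that ended with fry (adjusted p = 0.0897). Schwann cell markers had 2 of 8 up, or 3 adjusted over the list alone (adjusted p = 0.0467, and 0.479 with an estimated correlation), a call that ended with the stricter filter (adjusted p = 0.0626). Cdkn1a, a brake on the cell cycle, stood at 0.57 (adjusted p = 0.0533, higher in 9 of 9 pairs). It passed in 4 alternative settings (adjusted p = 8.39e-04 to 0.0364), among them the animal as a fixed block (adjusted p = 0.0065). The other lists had adjusted p of 0.0601 or more, and for the lymphocyte and endothelial lists median, mean or test differed in sign. Fibroblast markers were called up in 5 alternative settings (adjusted p = 0.0058 to 0.0363) and growth signalling in 4 (adjusted p = 0.0075 to 0.0443). The count was 2118 genes (1150 up, 968 down), reached in 1 of 100 splits with legs swapped within animals, the real one.

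**Figure D2:**
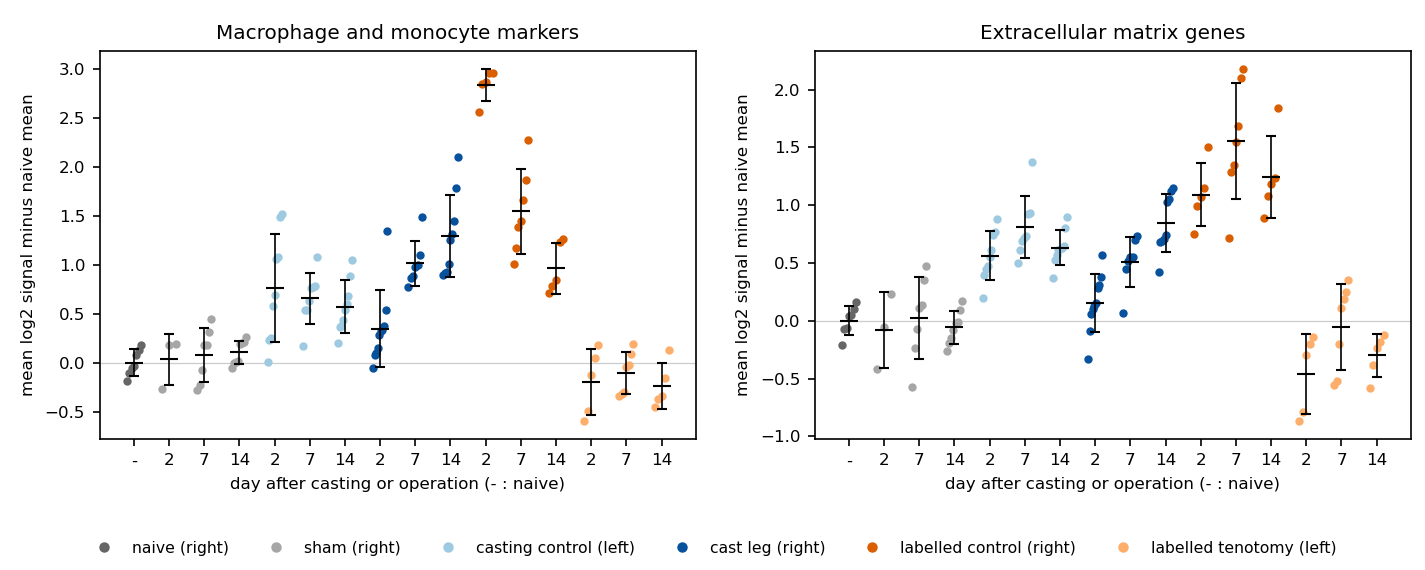
Mean log2 level of the macrophage and extracellular matrix lists relative to naive muscle in each array, by group and day, with group mean and SD. The right legs of the tenotomy animals, labelled control, stand highest for macrophage genes at day 2 (2.84, n = 5), and cast legs stand at 0.35 at day 2 (n = 10) and 1.01 at day 7 (n = 7).

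For tenotomy at day 2 the comparison asked how the leg labelled tenotomy (left) differed from the leg labelled control (right). Macrophage and monocyte markers were lower on the left in 25 of 26 (25 adjusted over the list alone), with a median of -3.16 and adjusted p = 9.71e-52 (adjusted p = 4.81e-05 with an estimated correlation). The pore-forming macrophage protein Mpeg1 stood at -5.59 and Gpnmb at -4.54. The level that departed from naive was the right leg, with a list mean of 2.84 (SD 0.16, n = 5) against -0.20 (SD 0.34, n = 5) on the left. Lysosomal genes had 25 of 32 down, the same adjusted over the list alone (adjusted p = 1.09e-24, and 4.81e-05 with an estimated correlation). Among them were the proteases Ctss (-3.96), Lgmn (-3.21) and Ctsl (-0.72, SE 0.11, adjusted p = 6.35e-08). Extracellular matrix genes had 30 of 34 down, or 32 adjusted over the list alone (adjusted p = 7.50e-19, and 0.0486 with an estimated correlation). The matricellular protein Postn stood at -4.22 and Lox at -3.74. Proliferation genes had 27 of 31 down (adjusted p = 2.53e-13, and 0.0039 with an estimated correlation) and complement genes 10 of 14 down and 1 up (adjusted p = 5.50e-08, and 0.0486 with an estimated correlation), each the same adjusted over the list alone. The actin ratio averaged -0.828 in these left legs (SD 0.172, n = 5) and -0.023 in the right legs (SD 0.296, n = 5).

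Energy and fibre genes ran the other way and were higher in the leg labelled tenotomy at day 2. All 44 oxidative phosphorylation genes (median 0.65, adjusted p = 2.47e-23, and 0.0982 with an estimated correlation) and all 19 tricarboxylic acid cycle genes (adjusted p = 6.99e-15, and 0.0257 with an estimated correlation) were higher. With the actin ratio as a covariate the oxidative phosphorylation median, right minus left, moved from -0.65 to -0.36 (SD over members 0.17), and 29 of 44 passed. Also higher were 18 of 22 fatty acid oxidation genes (adjusted p = 6.17e-12, and 0.0486 with an estimated correlation), with the same counts adjusted over each list alone. Glycolysis had 18 of 20 up and 1 down, or 19 and 1 adjusted over the list alone (adjusted p = 7.98e-08, and 0.121 with an estimated correlation). Fast fibre proteins had 16 of 20 up (19 adjusted over the list alone) and slow fibre proteins 10 of 17 (11 adjusted over the list alone), with adjusted p = 2.18e-06 and 5.67e-05 (adjusted p = 0.316 and 0.149 with an estimated correlation). Among the slow fibre proteins were Myl2 (3.01) and Myh7 (2.37, SE 0.40, adjusted p = 4.03e-07). The mean signal of Myh7 was 892.1 on the left (SD 813.8, n = 5), 182.7 on the right (SD 173.3, n = 5) and 3819 in naive muscle (SD 635.7, n = 7). Thus both legs lay below naive for slow fibre proteins, with list means of -1.21 on the left (SD 0.53) and -2.08 on the right (SD 0.41).

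The degradation genes at day 2 of tenotomy gave a mixed picture. Fbxo32 did not pass (-0.47, SE 0.26, adjusted p = 0.165, lower on the left in 5 of 5 pairs) except with quantile normalization (-0.63, adjusted p = 0.0477), and Trim63 was lower by -0.43 (adjusted p = 0.0423), a call lost without the animal block (adjusted p = 0.063). Of the ubiquitin ligases 13 of 27 were higher and 5 lower, or 14 and 6 adjusted over the list alone (adjusted p = 0.0108, and 0.184 with an estimated correlation). The 26S proteasome had 16 of 37 lower and 1 higher, or 17 and 1 adjusted over the list alone (adjusted p = 0.0391, and 0.667 with an estimated correlation), a call that ended with the stricter filter (adjusted p = 0.0967). Of the immunoproteasome genes 13 of 15 were lower, the same adjusted over the list alone (adjusted p = 7.58e-08, and 0.0557 with an estimated correlation). Extracellular proteases had 22 of 30 lower and 2 higher, or 23 and 2 adjusted over the list alone (adjusted p = 8.21e-07, and 0.0982 with an estimated correlation). Calpains and caspases had 11 of 20 lower and 4 higher (adjusted p = 0.0266, and 0.103 with an estimated correlation), and oxidative stress genes 12 of 19 lower and 3 higher (adjusted p = 0.0234, and 0.121 with an estimated correlation), each the same adjusted over the list alone. Fibroblast markers had 9 of 11 lower, or 9 lower and 1 higher adjusted over the list alone, and tenocyte markers 5 of 10, the same adjusted over the list alone (adjusted p = 2.69e-04 and 0.0354, and 0.149 and 0.402 with an estimated correlation). The calls of calpains, oxidative stress and tenocytes ended with the stricter filter (adjusted p = 0.0711, 0.0678 and 0.0846). Myog, which drives the differentiation of new fibres, was lower by -1.95 (SE 0.19, adjusted p = 3.72e-15), Mt2 by -2.70 (adjusted p = 3.43e-06), Cdkn1a by -1.46 (adjusted p = 7.46e-06) and Chrna1 by -0.57 (adjusted p = 0.00595). The other lists were uncalled (adjusted p of 0.15 or more), with signs that differed for the growth signalling, adipocyte and Schwann cell lists. Mechanical stress was called with quantile normalization (adjusted p = 0.0387), and autophagy, neuromuscular and regeneration genes with fry (adjusted p = 0.0191, 2.11e-04 and 0.0065). The count was 5885 genes (2556 higher, 3329 lower), against 3756 in the largest of the 15 other groupings that the 5 pairs allowed.

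At day 7 of tenotomy the same question gave matrix remodelling genes as the largest differences. The collagenase Mmp13 was lower on the left by -7.80 (SE 0.50, adjusted p = 1.20e-24), Cthrc1, a protein of healing matrix, by -5.87, and Serpina3n by -5.42, each in 7 of 7 pairs. Extracellular matrix genes had 30 of 34 lower, the same adjusted over the list alone (adjusted p = 6.68e-37, and 0.0045 with an estimated correlation). Extracellular proteases had 24 of 30 lower and 1 higher, or 24 and 2 adjusted over the list alone (adjusted p = 6.65e-19, and 0.0037 with an estimated correlation). Markers of tenocytes (8 of 10 lower, adjusted p = 9.18e-08, and 0.0227 with an estimated correlation), fibroblasts (10 of 11, adjusted p = 1.06e-10, and 0.0143 with an estimated correlation) and macrophages (25 of 26, adjusted p = 1.15e-27, and 0.0055 with an estimated correlation) moved with them, each with the same count adjusted over the list alone. Lysosomal genes had 20 of 32 lower and 3 higher, or 20 and 4 adjusted over the list alone (adjusted p = 8.09e-11, and 0.017 with an estimated correlation). Complement genes had 10 of 14 lower, or 12 adjusted over the list alone (adjusted p = 1.36e-09, and 0.0222 with an estimated correlation). Proliferation genes had 21 of 31 lower and 1 higher, or 25 and 1 adjusted over the list alone (adjusted p = 2.42e-08, and 0.0227 with an estimated correlation). Sarcolipin (Sln), a regulator of the calcium pump, stood at -3.90, and the slow light chain Myl3 (2.67) and Actc1 (2.47) were higher on the left.

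The oxidative lists kept their direction at day 7 of tenotomy, and the ligases showed small differences. Oxidative phosphorylation had 41 of 44 higher on the left, or 42 adjusted over the list alone (adjusted p = 1.91e-18, and 0.161 with an estimated correlation). With the actin ratio as a covariate the median, right minus left, moved from -0.46 to -0.24 (SD over members 0.15), and 24 of 44 passed. The tricarboxylic acid cycle had 17 of 19, or 18 adjusted over the list alone (adjusted p = 1.21e-13, and 0.0222 with an estimated correlation), and fatty acid oxidation 19 of 22, the same adjusted over the list alone (adjusted p = 1.44e-09, and 0.0655 with an estimated correlation). Glycolysis (13 of 20, or 17 adjusted over the list alone), fast fibre proteins (9 of 20, or 14 adjusted over the list alone) and slow fibre proteins (8 of 17, the same adjusted over the list alone) were higher with adjusted p = 6.66e-06, 1.38e-04 and 8.04e-05 (adjusted p = 0.206, 0.455 and 0.194 with an estimated correlation). The fast fibre call ended with quantile normalization (adjusted p = 0.0894). Ubiquitin ligases had 10 of 27 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0367, and 0.309 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.127). The proteasome list did not pass (10 higher, 2 lower, adjusted p = 0.0734). Immunoproteasome genes had 11 of 15 lower, the same adjusted over the list alone (adjusted p = 0.0012, and 0.267 with an estimated correlation). Fbxo32 (-0.28, adjusted p = 0.363) and Trim63 (0.15, adjusted p = 0.467) did not pass, whereas Mt2 (-2.84), Myog (-0.79), Ctsl (-0.37) and Cdkn1a (-0.62, adjusted p = 0.0339) were lower on the left. The last 2 of these calls ended with the mean of a gene's probe sets (adjusted p = 0.319 and 0.138). The growth signalling, lymphocyte and endothelial lists, not called, differed in sign between median, mean or test, and the other lists had adjusted p of 0.0734 or more. In some alternative settings the mechanical stress, calpain, neuromuscular, growth signalling and oxidative stress lists were called (adjusted p = 1.64e-07 to 0.0467). The count was 5277 genes (2336 higher, 2941 lower), reached in 1 of 64 groupings, the real one, with up to 4709 in the rest.

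At day 14 of tenotomy the matrix genes were still the clearest difference between the legs. Extracellular matrix genes had 32 of 34 lower on the left, or 33 adjusted over the list alone (adjusted p = 7.12e-42, and 0.0035 with an estimated correlation), with Cthrc1 at -4.94 (SE 0.49) and Postn at -3.73, and Mmp13 stood at -6.27. Extracellular proteases had 17 of 30 lower and 1 higher, or 19 and 1 adjusted over the list alone (adjusted p = 1.14e-12, and 0.019 with an estimated correlation). Markers of fibroblasts had 9 of 11 lower (10 adjusted over the list alone), of tenocytes 6 of 10 (7 adjusted over the list alone) and of macrophages 21 of 26 (22 adjusted over the list alone), with adjusted p = 3.52e-11, 6.21e-09 and 1.17e-16 (adjusted p = 0.019, 0.0235 and 0.0458 with an estimated correlation). Lysosomal genes had 17 of 32 lower and 1 higher, or 19 and 2 adjusted over the list alone (adjusted p = 3.81e-06, and 0.105 with an estimated correlation). Complement genes had 10 of 14 lower, the same adjusted over the list alone (adjusted p = 2.08e-07, and 0.0594 with an estimated correlation). Oxidative phosphorylation had 32 of 44 higher, or 38 adjusted over the list alone (adjusted p = 1.23e-15, and 0.204 with an estimated correlation). With the actin ratio as a covariate 6 of 44 passed, as the median, right minus left, moved from -0.38 to -0.11 (SD over members 0.14). The tricarboxylic acid cycle had 15 of 19, or 18 adjusted over the list alone, and fatty acid oxidation 16 of 22, or 17 adjusted over the list alone (adjusted p = 1.82e-10 and 5.42e-11, and 0.0594 for each with an estimated correlation). Sln was lower by -4.43, and Myl3 (1.49) and Myl2 (1.36) were higher.

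Smaller list differences at day 14 of tenotomy included the degradation genes. The proteasome had 6 of 37 higher and 1 lower and the ligases 7 of 27 higher and 3 lower, the same adjusted over each list alone (adjusted p = 0.0051 and 0.0377, and 0.566 and 0.357 with an estimated correlation). These calls ended with quantile normalization (adjusted p = 0.691 and 0.247). Glycolysis had 5 of 20 higher and fast fibre proteins 2 of 20, the same adjusted over each list alone (adjusted p = 9.57e-05 and 0.0019, and 0.328 and 0.566 with an estimated correlation). The fast fibre call ended with quantile normalization as well (adjusted p = 0.247), and the proteasome and fast fibre calls also with fry (adjusted p = 0.0951 and 0.103). Neuromuscular junction genes had 7 of 21 lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0328, and 0.128 with an estimated correlation). Calpains and caspases had 7 of 20 lower and 3 higher, or 10 and 3 adjusted over the list alone, and mechanical stress genes 9 of 24 lower and 1 higher, or 10 and 1 adjusted over the list alone (adjusted p = 0.0377 and 0.0453, and 0.128 and 0.566 with an estimated correlation). These 2 calls ended with the stricter filter (adjusted p = 0.0909 and 0.104), and the neuromuscular call with quantile normalization (adjusted p = 0.0561). Myog was lower by -0.91 (adjusted p = 1.56e-04), Mt2 by -1.40 (adjusted p = 0.032) and Cdkn1a by -0.75 (adjusted p = 0.0428), and the latter 2 calls ended on leaving out a single array (adjusted p up to 0.127 and 0.212). Fbxo32 (0.33, adjusted p = 0.418) and Trim63 (0.39, adjusted p = 0.0991) did not pass. Trim63 passed with the animal as a fixed block (0.49, adjusted p = 0.013) and with only the groups compared (0.39, adjusted p = 0.0052). For the oxidative stress, lymphocyte and Schwann cell lists median, mean or test differed in sign, none called, and the other lists had adjusted p of 0.0563 or more. The immunoproteasome list was called lower in 8 alternative settings (adjusted p = 0.0227 to 0.0479), and the slow fibre, proliferation and growth signalling lists were called in some (adjusted p = 0.0126 to 0.0485). The count was 3719 genes (1557 higher, 2162 lower), against 1390 in the largest of the 15 other groupings that the pairs allowed.

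**Figure D3:**
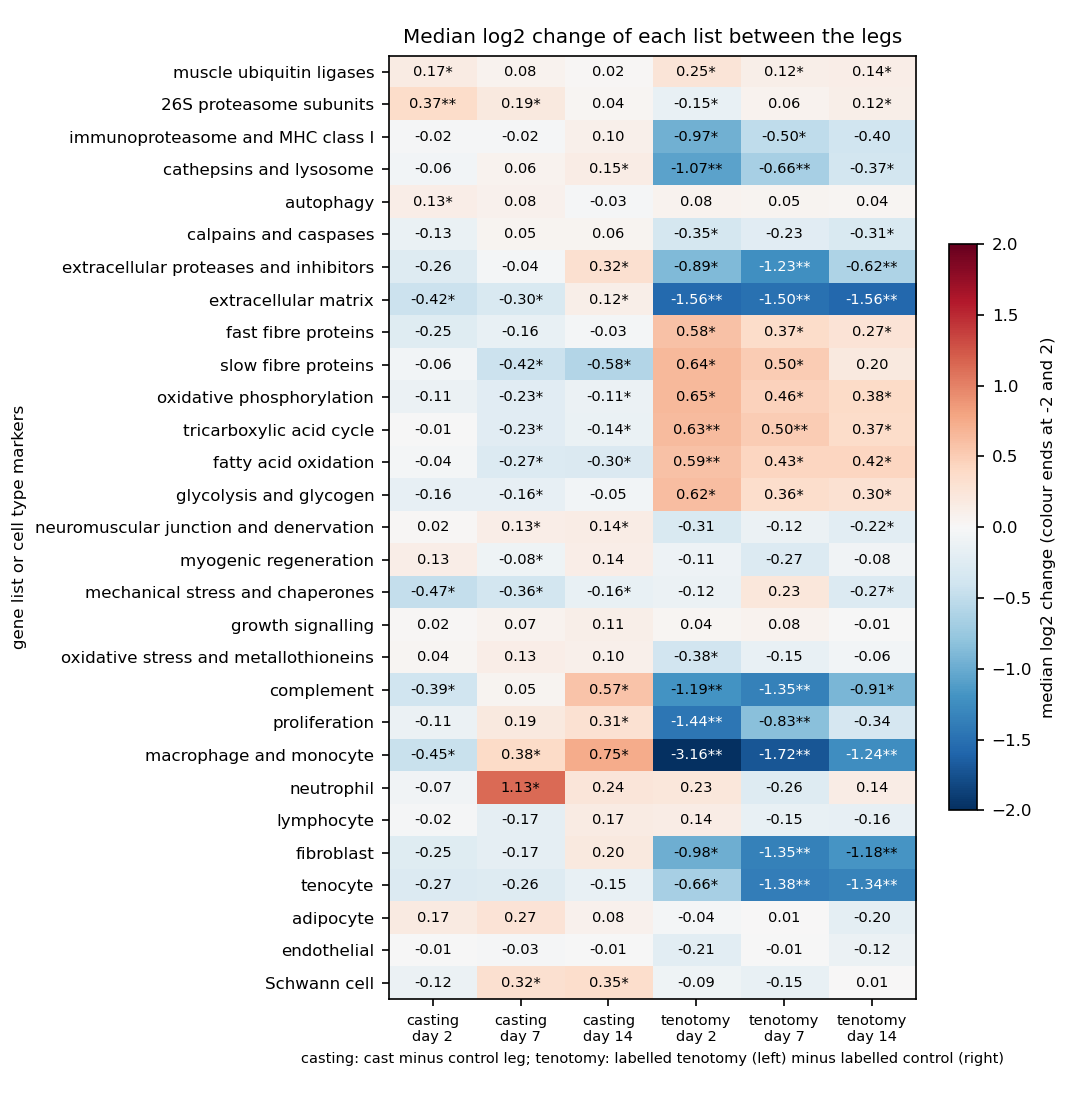
Median log2 difference between the legs (colour, log2 units, ends at -2 and 2) for 29 gene and marker lists (rows) in the casting and tenotomy comparisons at days 2, 7 and 14 (columns). An asterisk marks an adjusted p under 0.05 with the preset correlation and a double asterisk also with the estimated one, and the tenotomy columns are the leg labelled tenotomy (left) minus the leg labelled control (right).

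The models were compared directly by testing the tenotomy leg difference minus the casting leg difference. At day 2 the degradation genes that rose in the cast leg had a lower response in the tenotomy legs as labelled, with Fbxo32 at -1.92 (SE 0.33, adjusted p = 6.76e-07), Trim63 at -1.35 (SE 0.21, adjusted p = 9.66e-08) and Ctsl at -1.21 (SE 0.14, adjusted p = 4.43e-12). The proteasome list had 29 of 37 lower, or 29 lower and 1 higher adjusted over the list alone (adjusted p = 1.71e-12, and 0.103 with an estimated correlation). With the legs taken by side instead, right as operated, the values at day 2 were -0.98 for Fbxo32 (adjusted p = 0.0127), -0.50 for Trim63 (adjusted p = 0.0569) and 0.23 for Ctsl (adjusted p = 0.21). Trim63 by side passed in 6 alternative settings (adjusted p = 0.0057 to 0.048), among them the animal as a fixed block (-0.55, adjusted p = 0.0057). The proteasome then had 14 of 37 lower and 2 higher, or 16 and 2 adjusted over the list alone (adjusted p = 0.0016, and 0.425 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.251). Fbxo32 at day 2 thus passed as lower under each reading, although the reading by side lost the call on leaving out a single array (adjusted p = 0.0547). The directions of macrophage markers, Myh7 and Myog depended on the reading. Macrophage markers had 25 of 26 lower as labelled and 25 of 26 higher by side (adjusted p = 0.0038 and 8.54e-05 with an estimated correlation). Myh7 stood at 2.34 as labelled and -2.40 by side, and Myog at -1.74 and 2.16.

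The later days of the comparison between models followed the tenotomy legs. As labelled, Mmp13 stood at -8.40 at day 7 and -7.42 at day 14, and by side at 5.12 at day 14. Cthrc1 at day 7 stood at -5.41 as labelled and 6.34 by side. The fibrillin-associated protein Mfap4 stood at 4.71 by side at day 14, and Sln at 4.81. Extracellular matrix genes by side had 32, 31 and 31 of 34 higher at days 2, 7 and 14 (adjusted p = 0.0295, 3.98e-04 and 0.0025 with an estimated correlation), and as labelled 23, 24 and 32 of 34 lower (adjusted p = 0.268, 0.0814 and 0.0147 with an estimated correlation), with 1 higher at each of days 2 and 7. Fatty acid oxidation depended on the reading. As labelled it had 18 and 19 of 22 higher at days 7 and 14 (adjusted p = 0.0172 and 0.0147 with an estimated correlation), whereas by side it had 2 of 22 lower at each day and was not called (adjusted p = 0.132 and 0.0693, and 0.708 and 0.645 with an estimated correlation). By side it was called lower at day 7 without the arrays with a raised low end (adjusted p = 0.0476). At day 14 it was called lower without tenotomy day 14 replicate 1 or 3 or tenotomy control day 14 replicate 2 or 4 (adjusted p = 0.0012 to 0.033). Fbxo32 at day 7 was lower as labelled (-1.16, adjusted p = 0.002) and did not pass by side (-0.60, adjusted p = 0.187). The proteasome list by side at day 7 had 18 of 37 lower and 1 higher (adjusted p = 4.03e-10, and 0.133 with an estimated correlation). As labelled it had 13 lower and 3 higher and was not called (adjusted p = 0.0675, and 0.632 with an estimated correlation), but it was called lower in 5 alternative settings (adjusted p = 4.82e-05 to 0.0427). As labelled 5593, 4725 and 4599 genes passed at days 2, 7 and 14 (2498, 2034 and 1928 higher), and by side 5460, 3020 and 1305. The cohorts were separate animals with separate numbering, so that a difference between them could not be told from a difference between the models.

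Change over time was tested as the leg difference at day 14 minus that at day 2. In casting, Fbxo32 was lower at day 14 than at day 2 by -1.07 (SE 0.27, adjusted p = 0.0034) and Trim63 by -0.90 (SE 0.18, adjusted p = 0.00014), while Mt2 was higher by 2.58 (SE 0.52, adjusted p = 0.00017). In tenotomy as labelled, Trim63 was higher by 0.81 (SE 0.24, adjusted p = 0.022), Myh7 lower by -2.13 (SE 0.57, adjusted p = 0.0075), and Fbxo32 did not pass (0.80, SE 0.37, adjusted p = 0.2). The counts were 2286 genes in casting (1320 higher, 966 lower) and 1306 in tenotomy (847 higher, 459 lower), against at most 89 and 411 when days were exchanged at random.

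The legs labelled tenotomy were compared with sham-operated legs to ask how they differed from muscle after surgery alone. The legs labelled tenotomy were all left and the sham legs all right, and they came from separate cohorts. An effect of tendon cutting therefore cannot be told apart from side or cohort here, and which leg was cut is in doubt. Slow fibre genes had 9 of 17 lower than sham at day 2, or 10 lower and 2 higher adjusted over the list alone (adjusted p = 4.66e-08, and 0.204 with an estimated correlation). They were led by the slow tropomyosin Tpm3 (-3.24) and the slow troponins Tnnc1 (-3.05) and Tnnt1 (-2.60). At day 7 there were 10 of 17 lower and 1 higher (adjusted p = 6.56e-10, and 0.177 with an estimated correlation). Oxidative phosphorylation had 18 of 44 lower at day 2 and 26 at day 7, or 25 and 33 adjusted over the list alone (adjusted p = 3.18e-13 and 1.78e-11, and 0.456 and 0.679 with an estimated correlation). The tricarboxylic acid cycle had 13 of 19 lower at day 2, the same adjusted over the list alone, and fatty acid oxidation 10 of 22, or 14 lower and 1 higher adjusted over the list alone (adjusted p = 2.74e-09 each, and 0.204 each with an estimated correlation). At day 7 these lists had 9 of 19 and 12 of 22 lower with 2 higher each, or 10 and 12 lower with 2 and 3 higher adjusted over the list alone (adjusted p = 2.98e-04 and 4.61e-06, and 0.679 and 0.664 with an estimated correlation). The former call ended with quantile normalization (adjusted p = 0.0699). Fast fibre proteins had 9 of 20 lower and 1 higher at day 7 (adjusted p = 0.0023, and 0.875 with an estimated correlation), a direction that turned with quantile normalization (adjusted p = 0.38). Proteasome genes had 19 of 37 lower and 1 higher at day 7 (adjusted p = 6.56e-10, and 0.563 with an estimated correlation). At day 14 they had 17 lower and 1 higher (adjusted p = 2.35e-04, and 0.957 with an estimated correlation), a call that ended with the mean of a gene's probe sets (adjusted p = 0.263). Macrophage markers had 7 of 26 lower at day 14 (adjusted p = 0.0218, and 0.957 with an estimated correlation), a call that ended without tenotomy day 14 replicate 5 (adjusted p = 0.0631) or 1 (adjusted p = 0.0544). As labelled, connective tissue lists fell too. At day 2 they were fibroblast markers with 4 of 11 lower, tenocyte markers with 2 of 10 and extracellular matrix with 3 of 34, or 6, 3 and 2 adjusted over the list alone (adjusted p = 2.03e-04, 0.0045 and 4.84e-04, and 0.398, 0.456 and 0.878 with an estimated correlation). The tenocyte call ended without tenotomy day 2 replicate 3 (adjusted p = 0.114) and the matrix call without sham day 2 replicate 1 (adjusted p = 0.0827). Adipocyte markers had 4 of 10 lower at day 7, or 5 adjusted over the list alone (adjusted p = 0.0063, and 0.679 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.175). Mechanical stress genes had 4 of 24 lower and 2 higher at day 7, or 6 and 2 adjusted over the list alone (adjusted p = 0.0464, and 0.875 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.38). At day 14 fibroblast markers had 5 of 11 lower, adipocyte markers 4 of 10 and matrix genes 5 of 34 with 1 higher, the same adjusted over each list alone (adjusted p = 0.0218 each, and 0.957 each with an estimated correlation). These 3 calls ended without tenotomy day 14 replicate 5 (adjusted p = 0.0631, 0.0975 and 0.0975), the adipocyte call also without replicate 1 (adjusted p = 0.0687) and the matrix call without replicate 2 (adjusted p = 0.0708). Slow fibre genes were not called at day 14, with 6 of 17 lower and 2 higher (adjusted p = 0.0692), but passed in 5 alternative settings (adjusted p = 0.0061 to 0.0436). With fry the calls ended for matrix genes at day 2 (adjusted p = 0.204), fast fibre and mechanical stress genes at day 7 (adjusted p = 0.245 each) and matrix and macrophage genes at day 14 (adjusted p = 0.304 and 0.209). Among the largest rises were the growth inhibitor Ddit4 (2.94) and the clock gene Per2 (2.02) at day 2, and Per2 (2.94) and Per1 (2.15) at day 14. Sham muscle itself stood lower than naive at day 14 in these clock genes (-2.01 and -1.28), so that these differences are not separate from those of sham against naive. As labelled 1602, 3069 and 3326 genes passed at days 2, 7 and 14 (695, 1555 and 1604 higher), and with right legs as operated 5613, 6611 and 5758. By side matrix genes lay above sham (mean 1.25 and -0.05 from naive at day 14). Mpeg1 stood at 5.40 at day 2 and Mmp13 at 7.56 at day 7. The day 2 count fell to 1053 with only the groups compared and to 810 without sham day 2 replicate 2.

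Sham and naive muscle were compared to ask what the operation alone left behind. Genes of the circadian clock were among those that differed most. At day 7 the activators Arntl (1.45, SE 0.18, adjusted p = 2.27e-08) and Npas2 (1.68) were higher in sham and the repressors Per2 (-1.93) and Ciart (-1.85) and the output gene Dbp (-1.61) lower. At day 14 they stood at 1.28, 1.71, -2.01, -1.49 and -1.38, while genes outside the clock, among them the arrestin-like Arrdc2 (-1.87) and the reductase Cyb5r2 (1.48), differed by as much. Fatty acid oxidation was called lower at day 7 with no member passing (adjusted p = 0.0019, and 0.963 with an estimated correlation). Fast fibre proteins and oxidative phosphorylation were called higher with no member passing (adjusted p = 0.0392 each, and 0.963 with an estimated correlation), directions that turned with quantile normalization (adjusted p = 0.785 each). At day 14 there were 10 lists called lower and none with an estimated correlation, among them the tricarboxylic acid cycle with 1 of 19 members down, or 10 adjusted over the list alone (adjusted p = 1.49e-09, and 0.243 with an estimated correlation). With quantile normalization 7 of these 10 calls ended (adjusted p = 0.0566 to 0.638), and oxidative phosphorylation turned in direction (adjusted p = 0.638). Macrophage list means stayed near naive at 0.03, 0.08 and 0.11 (n = 3, 7 and 8). The counts were 0, 101 and 363 genes at days 2, 7 and 14 (40 and 163 higher at days 7 and 14). At day 2, with 3 sham arrays, limma found 0 genes past the adjusted test and 1120 with an unadjusted p under 0.05. Simulated differences of 1 on the log2 scale were found for 57 of 100 genes in this comparison.

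The control legs were compared with naive muscle to ask whether the untreated leg could stand for untreated muscle. In casting control legs, averaged over the days, the small GTPase Rrad was higher by 2.87, the matrix protein Thbs1 by 2.14 and the embryonic myosin Myh3 by 2.13, while the nuclear RNA Malat1 stood at -3.01 and the sulfur enzyme Mpst at -2.10. The list mean of oxidative phosphorylation was -0.52, -0.54 and -0.55 relative to naive at days 2, 7 and 14 (n = 9, 8 and 9), and that of macrophage markers 0.77, 0.66 and 0.57. In the legs labelled control (right) of tenotomy animals, Mmp13 (4.80), Cthrc1 (4.79), Postn (3.74) and Serpina3n (3.75) were higher and Myl2 (-3.66), Tpm3 (-3.49) and Myh7 (-3.18) lower. The counts were 5227 genes in casting control legs (3191 higher, 2036 lower) and 7277 in the legs labelled control of tenotomy (4338 higher, 2939 lower), or 4032 when left legs were taken as control. Control and naive legs came from different cohorts of animals and, for casting, from different sides.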

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

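The tests of swapped legs, of RNA quality in oxidative phosphorylation genes, of the sham operation and of the amount of slow muscle were chosen only after the result was seen, and the tests of RNA quality in macrophage genes and of time of day were set out before their results were seen. In 180 groups of 5 to 10 arrays tested for an array far from the others 14 were found, and chance gives about 1 in 20 groups. On the log2 scale, Fbxo32 was 10.71 in casting day 2 replicate 10 (median of the others 11.95) and Ctsl 10.94 in casting control day 2 replicate 4 (10.46). Foxo1 was 7.99 in casting day 14 replicate 8 (7.54), 8.00 in casting day 2 replicate 1 (7.53) and 8.36 in casting day 7 replicate 5 (7.49). Myh4 was 14.05 in casting control day 14 replicate 2 (12.97) and 14.01 in tenotomy day 14 replicate 4 (13.65), and Myh7 10.07 in casting control day 2 replicate 6 (12.11). Chrna1 was 9.70 in casting day 14 replicate 8 (7.71) and Myog 7.12 in casting day 7 replicate 1 (6.17). The actin 3' to 5' log2 ratio was -1.02 in casting control day 7 replicate 4 (-0.40). The distance from the naive mean was 0.67 in casting control day 7 replicate 1 (0.48), 0.70 in casting day 2 replicate 6 (0.54) and 0.60 in sham day 14 replicate 8 (0.43).

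Leg differences that differed between the models, as labelled, were counted and are listed here with adjusted p from limma. At day 2 they were Fbxo32 -1.92 (6.76e-07), Trim63 -1.35 (9.66e-08), Ctsl -1.21 (4.43e-12), Myh4 0.84 (0.0128), Myh7 2.34 (5.12e-05), Mt2 -1.97 (0.0073), Chrna1 -1.23 (1.72e-06), Myog -1.74 (2.15e-09) and Cdkn1a -1.74 (1.92e-05). At day 7 they were Fbxo32 -1.16 (0.002), Ctsl -0.58 (2.48e-04), Mt2 -3.92 (4.72e-08), Chrna1 -0.96 (1.08e-04) and Myog -0.75 (0.0071). At day 14 they were Ctsl -0.36 (0.041), Mt2 -3.25 (1.88e-05), Chrna1 -0.88 (9.88e-04), Myog -1.38 (2.65e-06) and Cdkn1a -1.32 (0.002). With quantile normalization Myh4 at day 2 was 0.11 (0.262). With the mean of a gene's probe sets Ctsl was -0.32 at day 7 (0.0871) and turned to 0.13 at day 14 (0.604), and the day 14 call ended in 8 other settings (0.0545 to 0.241). With the legs by side Mt2 was 3.43, 1.76 and -0.45 at days 2, 7 and 14 (2.40e-06, 0.0235 and 0.748), its day 7 call ending with array weights (0.0502) and without the arrays with a raised low end (0.0762), and Myh4, Ctsl and Chrna1 passed at none of these days. The counts of such genes were 5593, 4725 and 4599 at days 2, 7 and 14, and with the model exchanged at random between animals with both legs 1 of 100 splits, the real one, gave as many at each day (highest other 3163, 3346 and 2231). Between days 14 and 2 the leg difference changed in 2286 genes of casting and 1306 of tenotomy, again as many in 1 of 100 splits each (highest other 89 and 411). A share of 0.01 is the smallest that 100 splits can give. In the comparison of models the cohort goes with the model, and the splits cannot tell them apart.

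Other counts were set against other groupings of the same arrays. With legs swapped within animals, 1 of 100 splits gave as many genes as casting at day 2 (3893, highest other 2768) and at day 14 (2118, highest other 1633), 2 of 100 as casting at day 7 (1406, highest other 1508) and 1 of 64 as tenotomy at day 7 (5277, highest other 4709). For tenotomy at days 2 and 14 the 16 splits are too few for a share under 0.05 (5885 with highest other 3756, and 3719 with highest other 1390). Against sham, 1 of 56 splits gave as many at day 2 (1602, highest other 376) and 1 of 100 at days 7 and 14 (3069 with 793, and 3326 with 1614). For sham against naive, 100 of 100 splits reached the count of 0 at day 2 (highest other 7), and 1 of 100 the counts of 101 and 363 at days 7 and 14 (highest other 26 and 94). For the control legs against naive, 1 of 100 splits gave as many in casting (5227, highest other 2790) and in tenotomy (7277, highest other 3418). No other split gave as many except for casting at day 7 and sham at day 2.

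The right legs of the tenotomy animals, labelled control, differed far more from naive muscle than the left legs, labelled tenotomy. A difference in RNA quality, seen in the actin ratio (0.628, a signal outside the gene comparisons), was argued against as the whole cause for macrophage genes, since the macrophage median right minus left at day 2 was 3.16 without and 2.99 with the ratio as a covariate (SD over members 0.97, 25 of 26 still called). For oxidative phosphorylation genes it cannot be told apart from an effect of the leg. With the actin ratio as a covariate their median right minus left moved from -0.65 to -0.36, -0.46 to -0.24 and -0.38 to -0.11 at days 2, 7 and 14 (SD over members 0.17, 0.15 and 0.14), with 29, 24 and 6 of 44 still called. The actin ratio differed between the legs with the treatment, so that the covariate also removes part of a difference between the legs. An exchange of the tenotomy and control labels may explain the pattern, as the right leg was farther from naive in 16 of 16 pairs and the design text names the right tendon as cut. Tendon cutting itself, read with the right leg as operated, stays open as the biological explanation, and a response of the untouched right leg was not tested separately from it. The labels cannot settle which reading is right. Of the genes called in both models, 995, 117 and 48 went the same way as labelled at days 2, 7 and 14. Those going opposite ways were 1024, 601 and 938. Over all genes the leg differences of the models, as labelled, had a Pearson correlation of 0.12, -0.18 and -0.31. The models need not act alike, so this overlap does not decide between the readings.

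Clock genes differed between sham and naive muscle at days 7 and 14. Unoperated casting control legs differed from naive in clock score by 1.83, against 1.78 in sham at days 7 and 14 (share 1.02). They are a separate, cast cohort, so the sham operation stays open. Sham at day 2 stood at 0.74 (n = 3), and the left legs of tenotomy animals at 0.11, 0.75 and -0.45 at days 2, 7 and 14. A different collection time of naive and sham animals may explain the pattern. Of 8 clock genes not seen before 7 had the predicted sign, with Nr1d1 contrary (0.57). The tally is by sign alone and separates no causes. Clock, Tef, Hlf and Nr1d2 passed at day 7 or 14, while Cry1, Nfil3 and Bhlhe41 passed at neither day. Within animals the score also differed between legs (right minus left -0.49, SD 0.47, in 25 casting pairs and 0.44, SD 0.43, in 16 tenotomy pairs), which collection time cannot produce. The labels give no collection times.

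Slow fibre genes were called lower than in sham muscle in both legs of the tenotomy animals at days 2 and 7 and in the right legs at day 14, but not in the left legs at day 14 (cameraPR adjusted p = 0.0692). The list median of the left legs minus sham was -0.83, -1.17 and -0.50 at days 2, 7 and 14 (SD over members 1.34, 1.08 and 0.81), with 9, 10 and 6 of 17 called lower and 0, 1 and 2 higher. That of the right legs was -1.41, -1.31 and -0.76, with 11, 13 and 8 called lower and 0, 1 and 2 higher. With an estimated correlation the adjusted p were 0.204, 0.177 and 0.957 on the left and 0.0159, 0.0187 and 0.427 on the right. Less slow muscle taken at dissection in the tenotomy cohort may explain it (-0.50 at day 14) and cannot be told apart from an effect of tendon cutting on both legs, since the cohorts are separate animals. No table held a muscle weight or a dissection record.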

How the results depend on the processing

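Tests with the tenotomy legs by side, without the arrays with a raised low end and with the actin ratio as a covariate were chosen only after the results were seen. Of 317 recomputed counts 300 stayed within 1.5 times their value, 11 rose above and 6 fell below. Casting at day 7 gave 1406 genes, 2470 with array weights and 796 without the arrays with a raised low end, and the cause was not tested. Labelled tenotomy against sham at day 2 gave 1602 genes and 1053 with only the groups compared, a setting with fewer arrays. Leaving out 1 array of this comparison gave 810 to 1505, with 810 without sham day 2 replicate 2. Sham at day 2 against naive gave 0 genes, and 4 with no pseudocount, 1 with the stricter filter, 5 with only the groups compared, 1 with array weights, 1 without the arrays with a raised low end and 0 to 3 on leaving out 1 array. With the tenotomy legs by side, the models differed in 3020 and 1305 genes at days 7 and 14 and the tenotomy legs differed from sham in 5613, 6611 and 5758 genes. The control legs of tenotomy then differed from naive in 4032. These follow from the exchange of legs that defines the setting.

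Other counts on leaving out 1 array were 5260 to 5814 for tenotomy at day 2, 2842 to 3636 at day 14, 5170 to 5630 and 3960 to 4582 for tenotomy against casting at these days, 1046 to 1415 for tenotomy day 14 against day 2, 2800 to 3030 for tenotomy against sham at day 14 and 7154 to 7293 for the control legs of tenotomy against naive. With the animal as a fixed replicate block, on paired legs only, the counts were 3624, 1241 and 2057 for casting and 5821, 5224 and 2933 for tenotomy. Without a block they were 3533, 1182 and 1723 for casting. No count moved by over 1.5 times with either, while 40 named genes lost and 7 gained their call with the fixed block and 51 lost it without a block, and 4 list calls were lost and 2 gained with the fixed block and 1 gained without a block. With the actin ratio as a covariate tenotomy gave 4769, 4332 and 2732 genes.

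Among 1097 named gene results, 1028 were past the threshold, and the settings above gave 16677 values with the same direction and side, 604 that lost the call, 30 that gained it and 5 that reversed. With quantile normalization the difference between models at day 2 reversed for Car3 (-6.83e-04) and Des (-0.03). With the mean of a gene's probe sets Psmd9 reversed in casting at day 14 (0.11), Ctsl in tenotomy against casting at day 14 (0.13) and Ighm in tenotomy at day 14 (-0.02). The cause was not tested. That setting also ended 99 calls, against 8 with the larger pseudocount, 12 with no pseudocount, 14 with array weights, 24 with no filter, 39 with quantile normalization, 51 with only the groups compared and 66 without the arrays with a raised low end.

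Among 609 list results 265 were past the threshold with the preset correlation, and 202 of these calls ended with an estimated correlation. The test fry ended 36 calls and added 44, and quantile normalization ended 37 and added 15. With the latter 4 called lists reversed. Fast fibre proteins reversed in tenotomy against sham (adjusted p = 0.38) and sham against naive (0.785) at day 7. Oxidative phosphorylation did in sham against naive at days 7 (0.785) and 14 (0.638). This normalization moved the median of all genes by at most 0.098 in size (-0.098 for the control legs of tenotomy against naive). Signals near the low end of the arrays limit what can be said of weakly expressed genes.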

Other observations

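The test of a cooler cast leg was set out before its values were seen, with genes outside the lists. Its first criterion could not be evaluated, and the heat shock factor targets below bear on its second criterion alone. Growth signalling genes moved in both directions in the cast leg at day 2, with 5 up and 4 down of 27, or 6 and 4 adjusted over the list alone (adjusted p = 0.527). The translation repressor Eif4ebp1 rose by 0.88 (SE 0.12) and Fkbp5, a glucocorticoid target, by 0.72 (SE 0.19), while the insulin receptor substrate Irs1 fell by 0.77 (SE 0.14), each the same way in 9 of 9 pairs. Other cell types showed few differences there. Lymphocyte markers had 0 of 12 past limma's test (adjusted p = 0.947), endothelial markers 1 up and 3 down of 12 (adjusted p = 0.774) and adipocyte markers 1 up of 10 (adjusted p = 0.482). Oxidative stress genes at day 14 of casting had 6 up and 3 down of 19, the same adjusted over the list alone (adjusted p = 0.483).

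The cast leg at day 2 had lower heat shock genes and higher Cirbp, an RNA-binding protein induced by mild cold. A cooler cast leg is a candidate explanation. The heat shock factor targets outside the fixed lists had a median of -0.32 (SD over members 0.37, 11 genes), with 8 called lower and 1, Hspa4, higher (0.40, SE 0.06). Chaperones of the endoplasmic reticulum, which answer to other signals, were also lower, with a median of -0.55 (SD 0.45), 6 of 8 called lower and 1, Dnajb9, higher (0.49, SE 0.07). Cirbp stood at 1.83, 1.19 and 0.39 at days 2, 7 and 14, and Dnaja4, a co-chaperone, at -1.06, -0.89 and -0.63. The values leave the explanation open, since lower chaperones of both kinds are also what a fall in load or protein synthesis could give, and no temperature was recorded.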
